A study of Halobacterium salinarum NRC-1 with 16 samples.

How the data were processed

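The series comprises 16 two-colour microarrays of 8 strains. Per the labels, each strain was analysed at a single point of growth on a pair of arrays with Alexa 532 and Alexa 647 exchanged, against a standard mid-log reference RNA. The deposited scanner tables give, per the file headers, the mean spot intensity and the median local background intensity of both dyes in a high and a low scanner setting, for 10752 spots. The deposited value table holds log10 ratios whose construction is not given in the sources used here. Set against the scanner values of the high setting, the only one compared, it was close to the log10 of Alexa 532 over Alexa 647. It was not turned for the dye exchange, and its rows run along whole slide rows. In that order the log10 intensities of the 2 dyes accounted for 67.6% to 98.3% of its variance, and for 80% or more on 14 of 16 arrays. Part of its construction stays unknown, including any smoothing, which the slopes under 1 leave open. Its column medians in log10 units, with the strain in Alexa 532 and then in Alexa 647, were 0.0986 and 0.0678 for tbpA, 0.123 and 0.0395 for tbpC, 0.104 and 0.0925 for tbpD, 0.0640 and 0.146 for tfbA, 0.0915 and 0.0839 for tfbB, 0.124 and 0.0867 for tfbC, 0.0490 and 0.00892 for tfbD, and 0.0970 and 0.104 for tfbG, so the columns were not centred.

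The high setting was used, with normexp background correction (offset 50) and 1 loess curve per array in limma 3.58.1 (R 4.3.3). The log2 ratio was turned to strain over reference by the dyes in the labels, the 4 spots of a feature were averaged, and the 2 arrays of a strain were averaged to 1 value. A symbol table for the probes names 532 spots, 133 features with 1 symbol each and none with several; other features have no name here and are given by the number of their first spot, at most 2 per direction and comparison. Positions with all 4 spots empty in the value table on at least 6 arrays, 160 features, were taken as unfilled and left out, leaving 2528 tested. A feature was called well above the unfilled positions on an array and channel when its mean intensity passed their 95th percentile. By that measure 443 to 1472 features stood out in Alexa 532 and 1068 to 2156 in Alexa 647. Spots below their local background made up 10.9% to 67.6% in Alexa 532. At most 318 spots per array and channel were saturated. In the tfbG comparison, where a named gene was not well above the unfilled positions on any array of 1 group, the fold is a lower bound from single-channel levels after loess and Aquantile normalization, with the dim group at the higher of its own signal and the lowest signal of a feature that stood out. It was not used for carB, where it exceeded the fitted ratio, and no fold is given where both groups were dim.

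The tests were limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05: an intercept over the 7 knockouts (shared change against the reference), the 3 tbp against the 4 tfb knockouts, the tfbG strain against the 7 knockouts, and each knockout against the other 6. A lone strain is assumed to vary like the others. p-values measure the spread between strains, each 1 culture. Single strains against the reference were only counted at a 2-fold change. Of 25 gene lists fixed before the data were examined, 7 had at least 5 measured genes and were tested with camera (preset and estimated correlation) and fry, and by the percentile among 10000 random lists matched on intensity; 9 had fewer genes and 9 had none. Lists were matched on symbols alone, since product text and replicons were not used here, and the lists of plasmid genes were therefore empty. Named genes followed a rule set before the data were examined: for the shared and the tfbG comparison the 10 highest and 10 lowest named genes past the threshold that had 1 sign in all 7 knockouts or lay outside their range, the 2 highest and lowest unnamed features, and up to 2 further members of each list per direction; for each knockout the 3 highest and lowest past the threshold; where fewer than 3 passed, those of smallest p; and named genes changed 2-fold in a strain. Similarity was the Pearson correlation of strain profiles after centring, beside 100 simulations, and the relation to OD600 used exact permutation.

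The code was tested on simulated data. Among 200 of 2528 features changed by a log2 value of 1, 100% were recovered for the shared change, 87.5% for tbp against tfb knockouts, 69.5% for the tfbG strain and 60.5% for 1 knockout; at 0.5 it was 89.0%, 22.5%, 0% and 0%. In the strain channel of 200 features the signal above local background was made 2-fold (log2 of 1). Spots at or below background got no change. The change came out in the right direction in 97.6% of values, with a median log2 of 0.57. That median mixes compressed ratios with spots that got little or no change, and their parts were not separated. The recovered shares refer to measured ratios and may overstate those for true changes. Alternatives covered the background correction, the normalization, the deposited values, dim features, single dye orientations, the mean or median of spots, the eBayes prior, arrays as units, left-out strains and OD600 as a covariate. Chosen after seeing the data were the low scanner setting, the centred deposited values, a loess curve per printed block, only features above the unfilled positions, leaving out tfbB and tfbD, and named genes as the background of camera.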

Results

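Transcript levels were measured in 8 strains of Halobacterium salinarum NRC-1, an extremely halophilic archaeon whose RNA polymerase is recruited to promoters by TATA-binding proteins (tbp genes) and TFIIB-like factors (tfb genes), both present as families of several members. In 7 strains 1 general factor gene was knocked out: tbpA, tbpC, tbpD, tfbA, tfbB, tfbC or tfbD. The eighth strain expressed a histidine-tagged tfbG from a plasmid. Each strain gave 1 RNA sample, hybridised against a standard wild-type reference RNA on 2 two-colour arrays with the dyes exchanged, 16 arrays in all. The knockout cultures were harvested at an OD600 of 0.586 to 0.719, the reference in mid-log phase at 0.5 to 0.6, and the tfbG culture in late stationary phase. The arrays carried 2688 features of 4 spots, of which 2528 were tested and 133 had a gene symbol, so most changed features below have no name here. The 2 arrays of a strain hold the same RNA, so a strain is 1 value and the 7 knockouts are the replicates of the fits. Strain against reference has no replicate check for any single strain, and nothing in the labels says that cultures were repeated. The number of arrays limits the precision.

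In a knockout series the targeted genes check the labels, but none of the tbp or tfb genes was among the 133 symbols, and the targeted genes were not analysed here. The dye exchange gave a partial check. Over the brightest 20% of features, 506 in number, the deviation of a strain from the knockouts (the others, for a knockout) on 1 array correlated with that on its dye-exchanged array at r = 0.80 in the tfbG strain, 0.35 in the tbpD knockout and 0.29 in the tbpA knockout. Over all features the same measure was lower, 0.14 in tfbG, 0.22 in tbpA, 0.03 in tbpD and -0.13 in tfbA. In the brightest features it was 0.15 in the tfbA, 0.03 in the tbpC, -0.10 in the tfbC, -0.13 in the tfbB and -0.25 in the tfbD knockout, across features, which are not independent replicates. For tfbB and tfbD a wrongly assigned dye would have brought feature 4433, low in every knockout, near 0 or turned its sign, and it stood at -2.02 and -2.13. A wrongly assigned array cannot be excluded, and that doubt covers the counts and features given for these strains below. A strong dye effect remained on every array pair: over all features the 2 turned ratios of a strain correlated negatively, from -0.20 in tbpC to -0.59 in tbpD.

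Few features differed 2-fold from the reference with the same direction on both arrays, and most were lower in the strain. In the tfbG strain 25 features were higher and 35 lower, and in the tfbD strain 8 were higher and 19 lower. The tbpA strain had 21 such features in all, tfbB 12, tbpC 11, tfbC 11, tbpD 6 and tfbA 5. The named ones were few. carB, the large subunit of carbamoyl-phosphate synthase, stood at a log2 ratio of 1.01 in the tbpA and 1.08 in the tbpC knockout. phoU, a regulator of phosphate uptake, stood at -1.09 in the tbpA knockout and -1.09 in the tfbG strain. In the tfbG strain gdhA1, a glutamate dehydrogenase, stood at -1.13, with its strain channel well above the unfilled positions on 1 of 2 arrays. hutG, of histidine degradation, was higher in the tfbG strain and gatC lower in the tfbA knockout, but hutG was not well above the unfilled positions in either channel, nor gatC in the strain channel, and no fold is given. The total over the 8 strains, 153, became 48 with 2-fold required on both arrays and 15 without background correction. These counts are descriptions of single RNA samples. They are smaller than the number of features whose arrays differed by as much between the dye orientations, 37 in tbpC to 189 in tbpD among the knockouts and 265 in tfbG, where the measure is the absolute value of 0.5 times the difference of the 2 log2 ratios.

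The 7 knockouts as a class had more mRNA than the reference for a few named genes, among them carB, gdhA1 and a pair of ribosomal protein genes, rpl12p and rpmC. carB rose by 0.75 on the log2 scale (SE 0.08, 1.68-fold, adjusted p = 0.00099 in limma), with each of the 7 knockouts above the reference. gdhA1 rose by 0.50 (SE 0.07, 1.41-fold), rpl12p, ribosomal protein L12, by 0.47 (SE 0.05, 1.38-fold) and rpmC, ribosomal protein L29, by 0.46 (SE 0.07, 1.38-fold), each in 7 of 7 strains. The purine synthesis gene purF rose by 0.37 (SE 0.07), the second glutamate dehydrogenase gdhA2 by 0.34, eno, the glycolytic enzyme enolase, by 0.24 and sucC, a subunit of succinyl-CoA synthetase, by 0.24, again in 7 of 7 strains. With the strain in Alexa 532 and then in Alexa 647, purF stood at 0.12 and 0.61 and eno at 0.02 and 0.46. Among 21 alternatives sucC lost its call in 10, eno in 6, purF in 5, arcC in 4 and gdhA2 in 3. Of genes given below, hisF lost its call in 11 of 21 and turned in 1, and purL lost it in 5 of 21. pyrF lost its call in 8 of 19, and truA in 9 of 19 with 1 turn. gyrA, a subunit of DNA gyrase, rose by 0.56 (SE 0.09), but its strain channel was well above the unfilled positions on 7 of 14 arrays. Among the named genes past the threshold, arcC, the carbamate kinase of arginine fermentation, was the one below the reference in all 7 strains; it fell by 0.37 (SE 0.07, adjusted p = 0.0098). truA, a tRNA pseudouridine synthase outside the naming rule and added after its values were seen, stood at -0.45 (adjusted p = 0.029), but at -1.57 with the strain in Alexa 532 and 0.66 in Alexa 647, with its strain channel well above the unfilled positions on 3 of 14 arrays. The largest change belonged to a feature without a symbol, number 4433, which fell by 1.99 (SE 0.08, 3.96-fold, adjusted p = 5.97e-07 in limma) with the strains between -2.28 and -1.62. Its strain channel was well above the unfilled positions on 6 of 14 knockout arrays, so the fold is not exact. Under the alternatives its value lay between -2.23 and -1.25. Feature 5161, also without a symbol, fell by 1.03, and feature 227 rose by 0.73. Of 14 knockout arrays, the strain channel was well above the unfilled positions on 6 for 5161, 7 for 227 and 8 for gdhA2. The reference channel was so on 10, 4 and 7. Feature 421 was also higher, but its reference channel was well above the unfilled positions on 0 of 14 knockout arrays, and no fold is given.

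In total 179 features were higher and 118 lower in the knockouts than in the reference by limma with Benjamini-Hochberg adjustment, and 223 of these 297 went the same way in both dye orientations. Among the named genes 12 were higher and 3 lower. Of the purine and pyrimidine synthesis list, 2 of 10 genes rose (purF, and purL by 0.34 in 6 of 7 strains), 1 fell (pyrF, which was not well above the unfilled positions in any knockout array), and 7 did not pass; 4 passed when adjusted over the list alone. In the citric acid cycle list sucC rose, 5 of 6 genes did not pass, and 1 passed when adjusted over the list alone. Of 11 amino acid synthesis genes hisF passed, with 0.24, and its direction differed between the dye orientations, -0.05 with the strain in Alexa 532 and 0.53 in Alexa 647. gyrA passed among 5 genes of DNA replication and cell division, 2 when adjusted over the list alone, and none of 12 aminoacyl-tRNA synthetases, 11 chemotaxis genes or 6 genes of chaperones and proteases did, although 2 of the chaperone and protease list passed when adjusted over the list alone. No list shifted as a whole by camera (smallest adjusted p = 0.13, and 0.26 with an estimated correlation), while fry, which does not compare a list with other genes, gave adjusted p = 0.012 for purine and pyrimidine synthesis, 0.011 for the citric acid cycle and 0.013 for DNA replication, all upward. The reference is 1 RNA whose own spread is left out of these tests. Positions taken as unfilled from their empty deposited values passed in 32 of 160 cases in a separate fit of the same form. That fit was adjusted over the unfilled positions alone, so its threshold is not that of the 2528 features. Calls of dim features carry that background. Without the tbpA, tbpC, tfbA, tfbB or tfbC knockout the shared count fell to 145, 143, 173, 177 and 139.

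**Figure D1:**
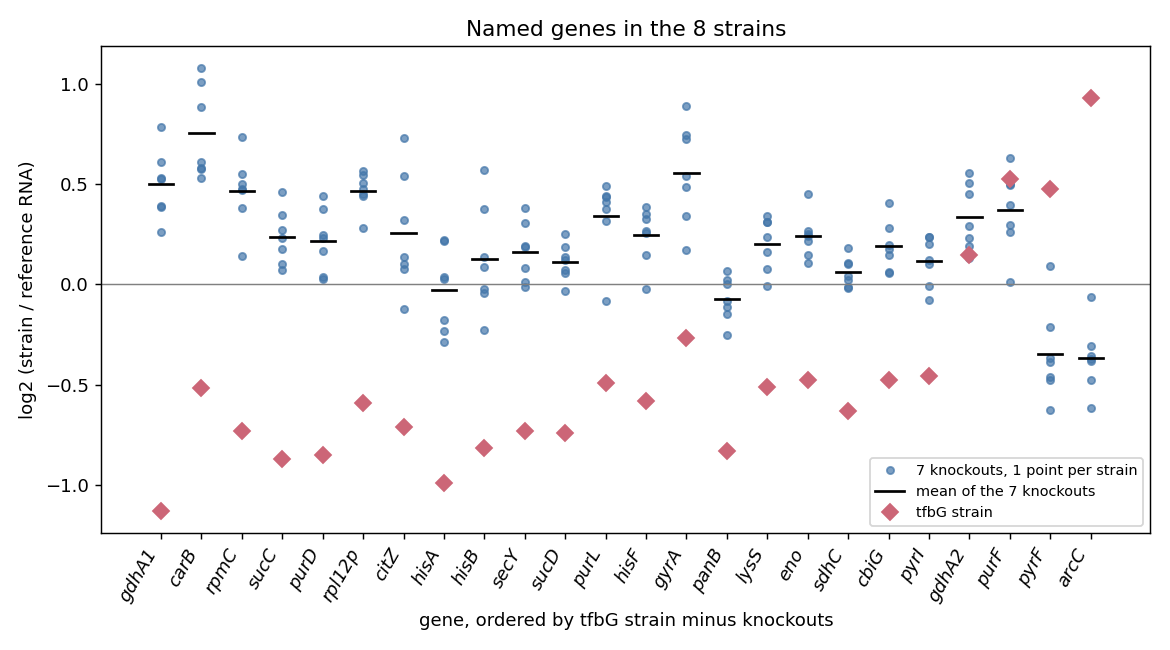
Log2 ratio of strain over reference RNA for the named genes of the shared and tfbG comparisons, 1 column per gene. Blue points are the 7 knockouts, the black line their mean and the red diamond the tfbG strain, each value the mean of 2 dye-exchanged arrays; for gdhA1 the knockouts lie between 0.26 and 0.79 and the tfbG strain at -1.13.

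No feature separated the 3 tbp knockouts from the 4 tfb knockouts. limma gave 0 features past the threshold and 185 at an unadjusted p under 0.05, with a smallest adjusted p of 0.471. Feature 1921 had the smallest p, with a difference of -0.82 (SE 0.15, tbp minus tfb), and feature 791 stood at -0.54 (SE 0.11). carB stood at 0.24 (adjusted p = 0.82), gdhA1 at 0.09 and rpl12p at 0.06. None of the 7 lists differed, the smallest adjusted p being 0.607 by camera and 0.715 with an estimated correlation. In simulated data of this size 87.5% of features with a measured log2 difference of 1 and 22.5% of those with 0.5 were found. A 2-fold change of the signal above background was measured at a median log2 of only 0.57, spots that got no change included. Differences of 2-fold between the families could therefore pass unseen.

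The tfbG strain, in late stationary phase, had less mRNA than the knockouts for single named genes of several pathways, and for 4 of the 6 measured citric acid cycle genes. gdhA1 fell by 1.63 on the log2 scale (SE 0.19, 3.09-fold, adjusted p = 0.0022 in limma). sucC stood at -1.11 (SE 0.17, 2.15-fold) and sucD, of the same enzyme, at -0.85 (SE 0.15). citZ, citrate synthase, stood at -0.97 (SE 0.28, adjusted p = 0.048), losing its call in 6 of 21 alternatives. sdhC, of succinate dehydrogenase, stood at -0.69 (SE 0.14), with -0.16 in the Alexa 532 and -1.22 in the Alexa 647 orientation. rpmC fell by 1.19 (SE 0.20, 2.29-fold) and rpl12p by 1.06 (SE 0.15, 2.08-fold), and secY, the membrane channel for protein export, fell by 0.89 (SE 0.18). The tfbG signal of gdhA1, citZ, sdhC, rpmC and secY was well above the unfilled positions on 1 of the 2 tfbG arrays. The same held for purD, purL and features 547 and 45 below, so these values are not exact. carB was also lower (adjusted p = 0.0074), but its tfbG signal was not well above the unfilled positions on either array and no fold is given. For the same reason only a bound is given for hisA of histidine synthesis, at least 1.59-fold lower, and for lysS, lysyl-tRNA synthetase, at least 1.36-fold lower. These bounds belong to the processing described above and do not hold under every alternative. At the weakest the fitted log2 difference was -0.35 for hisA and -0.22 for lysS. hisA lost its call in 4 of 19 alternatives and lysS in 4 of 21. purD and purL of purine synthesis stood at -1.07 and -0.83, and purD differed between the dye orientations, -2.02 with the strain in Alexa 532 and -0.11 in Alexa 647. The named genes that rose were arcC, by 1.30 (SE 0.19, 2.45-fold, adjusted p = 0.0034), and pyrF, which was not well above the unfilled positions in any strain. pyrF lost its call in 14 of 19 alternatives. Of features without a symbol, 5161 rose by 1.92, and 547 and 45 fell by 1.96 and 1.80. With the strain in Alexa 532 and then in Alexa 647, 547 stood at -2.63 and -1.29 and 45 at -2.71 and -0.90. Feature 2505 was also higher, but was well above the unfilled positions on 0 tfbG arrays and on 1 of 14 knockout arrays in the strain channel, and no fold is given.

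In total 101 features were higher and 229 lower in the tfbG strain, 310 of the 330 going the same way in both dye orientations, and 22 of them were named, 2 higher and 20 lower. Of the citric acid cycle list 4 of 6 genes fell and icd and mdh did not pass, at -0.21 and -0.43; the list median was -0.77 and camera gave adjusted p = 0.0023, with adjusted p = 0.072 with an estimated correlation, which does not pass. Of 11 amino acid synthesis genes hisA, hisB (-0.94, SE 0.26) and hisF (-0.82) fell and 8 did not pass, 4 passing when adjusted over the list alone. The dye orientations differed for hisF, at -1.61 and -0.04, and hisB lost its call in 11 of 21 alternatives, with values from -1.08 to -0.10, and pyrI of the next list in 9. The tfbG signal of hisB and hisF was well above the unfilled positions on 1 of 2 tfbG arrays. Of the purine and pyrimidine list purD, purL and pyrI (-0.57) fell, pyrF rose and 6 did not pass, 4 passing when adjusted over the list alone. Of 12 aminoacyl-tRNA synthetases lysS fell and 11 did not pass. None of 5 genes of DNA replication passed, 1 when adjusted over the list alone. Of 6 genes in the list of chaperones and proteases panB fell by 0.76. Its tfbG signal was well above the unfilled positions on 1 of 2 tfbG arrays. It entered the list by its symbol alone, and its product was not checked. The proteasome subunits psmA and psmB stood at 0.13 and 0.26. No chemotaxis gene passed, also when adjusted over the list alone, the largest difference being 0.72 for htr8 (adjusted p = 0.11), and camera gave adjusted p = 0.19 for the list. fry gave adjusted p = 0.00017 for the citric acid cycle, 0.024 for amino acid synthesis and 0.034 for the aminoacyl-tRNA synthetases, all downward. By camera the last 2 lists did not pass, with adjusted p = 0.187 and 0.198, and 0.293 for each with an estimated correlation. Against the reference alone the citric acid cycle median of the tfbG strain, -0.67, lay at the 0.23 percentile of random lists matched on intensity, amino acid synthesis at the 0.51 and chemotaxis, with a median of 0.17, at the 98.1 percentile. Single knockouts reached similar places: purine and pyrimidine synthesis lay at the 99.8 percentile in tbpC, 99.5 in tfbD, 97.7 in tbpA and 97.5 in tfbA, the aminoacyl-tRNA synthetases at the 99.1 in tfbB and amino acid synthesis at the 0.21 in tbpA.

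The lone tfbG strain was assumed to vary like the knockouts. Growth phase, plasmid and tagged factor were combined in 1 culture, so that this comparison cannot attribute a difference to any of them. In the labels the tfbG arrays also have higher array numbers than every knockout array. Whether they were hybridised apart, or with the same reference preparation, is not known here. Unfilled positions were higher in the tfbG strain by a median of 0.57, a shift that the dimmest features share. The tfbG array with the strain in Alexa 532 had the highest median Alexa 532 background of all arrays, 11071 against at most 7211, and 65.0% of its Alexa 532 spots below background. With only arrays of that orientation the count was 657, and with only those with the strain in Alexa 647 it was 53.

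**Figure D2:**
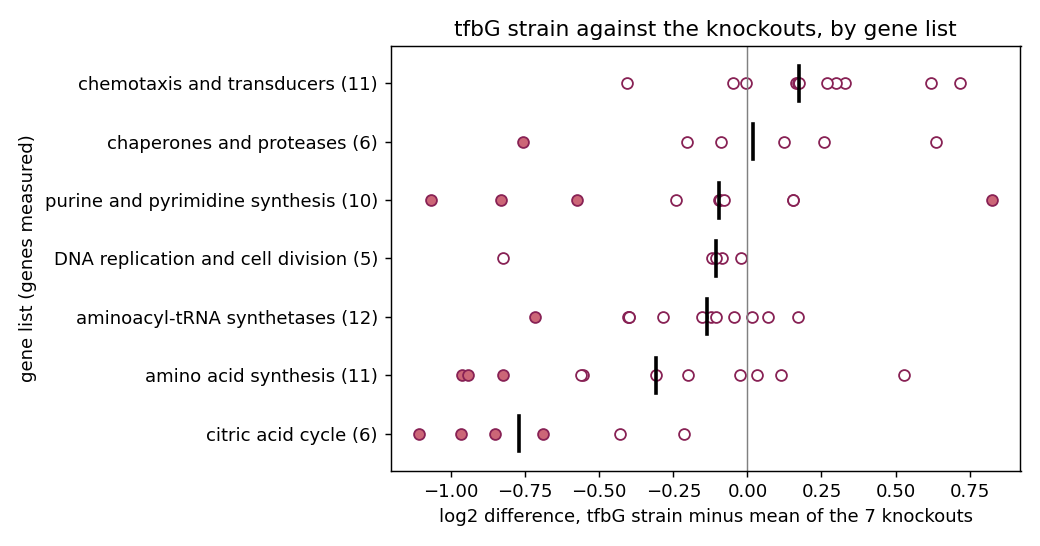
Log2 difference between the tfbG strain and the mean of the 7 knockouts for the members of the 7 gene lists with at least 5 measured genes. Each circle is a gene, filled where its adjusted p in limma was below 0.05, and the black bar is the list median, -0.77 for the citric acid cycle.

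Single knockouts differed little from the other 6. By limma 1 feature passed over all 7 fits: number 3953, without a symbol, which fell by 1.32 in the tfbD knockout (SE 0.14, 2.50-fold, adjusted p = 0.016), with -2.03 on the Alexa 532 array and -0.61 on the Alexa 647 array. At an unadjusted p under 0.05 the counts were 446 features in tfbD, 149 in tbpA, 137 in tbpD, 98 in tbpC, 80 in tfbC, 74 in tfbB and 61 in tfbA. The features of smallest p that did not pass were 2589 in tbpA (adjusted p = 0.367), 3261 in tbpD (0.397), 4233 in tfbA (0.458), 355 in tfbB (0.539), 4733 in tbpC (0.995) and 4491 in tfbC (0.99996). Of these 3261, 4233, 355 and 4733 were well above the unfilled positions on 0 of 14 knockout arrays in either channel and 2589 on 1 of 14 in the strain channel, so no differences are given for them; 4491 stood at 0.82. gatC, a subunit of the amidotransferase that makes charged tRNAs, was among the 5 of smallest p in tfbA, but its strain channel was not well above the unfilled positions on any knockout array. Feature 3953 was well above them on 6 of 14 knockout arrays in the strain channel and on 4 of 14 in the reference channel. It was not called under median centring, with the deposited values as given or centred, or with Alexa 647 arrays alone. The same held without the tbpC, tbpD, tfbB or tfbC knockout. With the dimmest 25% of features left out, 73 features passed in the tfbD knockout, 69 of them lower, and on its Alexa 532 array alone 554 did, against 0 on the Alexa 647 array. No list shifted in a single knockout by camera, the smallest adjusted p being 0.143, in tfbB for both purine and pyrimidine synthesis (lower) and the aminoacyl-tRNA synthetases (higher), and 0.370 for each with an estimated correlation. Adjusted over the list alone, 4 chemotaxis genes and 2 aminoacyl-tRNA synthetases passed in tfbD and 1 gene of DNA replication in tfbC. In simulated data 60.5% of measured log2 differences of 1 and 0% of those of 0.5 were found. A 2-fold change of the signal above background was measured at a median of 0.57, spots that got no change included. Differences of 2-fold in a single knockout could therefore pass unseen.

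The most similar knockout profiles were those of tbpA and tbpC, and no test related similarity to the families. After removal of the mean of the 7 knockouts, the pair correlated at r = 0.30 across features, tbpD and tfbA at 0.21 and tfbA and tfbB at 0.10. tbpA and tbpD stood lowest, at -0.39. The tbpA and tbpC arrays with the strain in Alexa 647 had 67.6% and 60.3% of Alexa 532 spots below background. Whether array quality had a part in their similarity was not tested. The tfbD array in that orientation had 67.5%, and tfbD correlated with tbpA at -0.25 and with tbpC at -0.20. Simulated independent strains gave a mean of -0.17 with a range of -0.26 to -0.08, and 5 of 21 pairs lay above and 6 below it. The mean was -0.11 over 9 pairs within a family and -0.20 over 12 pairs between families. These are correlations across features, which are not independent replicates. The simulations drew each feature independently, so their range can be too narrow where arrays share technical effects.

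The list means of the knockouts had no detectable relation to culture density. The strongest was the citric acid cycle, with Pearson's r = -0.61 against OD600 over 7 strains (exact permutation p = 0.144, adjusted p = 0.659 over 7 lists, two-sided) and Spearman's rho = -0.57 (exact permutation p = 0.200, adjusted p = 0.871). Without the tbpA and tfbD knockouts, the 2 strains farthest from the median OD600, r was -0.00436. The other 6 lists had adjusted exact permutation p of 0.659 or more.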

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

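All tests in this part except the splits of the knockouts and the growth phase were chosen after the results were seen.

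In 10 genes the averages of the tfbG strain and of the knockouts over both dye orientations lay on opposite sides of the reference, with both the shared change and the difference between tfbG strain and knockouts past the threshold of limma. The differences, tfbG strain minus knockouts, were -1.63 for gdhA1, -1.19 for rpmC, -1.11 for sucC, -1.06 for rpl12p, -0.83 for purL, -0.82 for hisF and -0.71 for eno, against 1.30 for arcC. hisF lay on the same side as the knockouts within each orientation, so its sides are not established. With the strain in Alexa 647 the knockouts stood at -0.31 for pyrF and the tfbG strain differed from them by 0.11, which left it on their side. For carB in that orientation the knockouts stood at 1.06 and the difference was -1.05, which put the tfbG strain near the reference. The fitted values of carB, -1.27, and pyrF, 0.82, are not exact, since carB was not well above the unfilled positions in the tfbG strain and pyrF in no strain. The tfbG signal of gdhA1, rpmC, purL, hisF and eno was well above them on 1 of 2 tfbG arrays. Among 34 values examined over the 7 knockouts, 1 had a strain far from the rest: purL stood at -0.0805 in the tfbB knockout and at 0.32 or more in the other 6. Chance flags about 1 in 20 such groups. Unfilled positions, which were outside the comparisons, passed the threshold in 32 cases when fitted on their own for the shared change. Fitted on their own for the tfbG strain, they differed from the knockouts by a median of 0.57.

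The shared change of the knockouts had 3 technical explanations to weigh. A shift of dim features, seen in the unfilled positions, is not decided for the brighter features. Of the 1264 features above the median intensity 13.8% passed, but not all of these were clear of the unfilled positions. In Alexa 532 only 443 to 1472 features per array stood out. For the dimmest 25% such a shift may account for the calls, as 20% of unfilled positions passed against 8.86% of those features. The unfilled positions were fitted and adjusted on their own, so the 2 shares are not at the same threshold. A dye effect of equal size in both orientations cancels in the average of the 2 arrays, and one of unequal size would turn the ratio between them. Of the called features 75.1% went the same way in both. Calling on the average itself favours features whose orientations agree, and no expected share was worked out, so this share does not decide. Over all features the knockout mean correlated at -0.59 between orientations and over the brightest 20% at -0.000213. A peculiarity of the single reference RNA cannot be told apart from a knockout effect: the tfbG strain, signed by the knockouts' direction, had a median of -0.19 over these features against 0.33 in the knockouts, but it was grown to another phase. The loss of a general factor stays open beside it, as do other differences between the knockouts as a class and the reference. Culture density was one, at an OD600 of 0.586 to 0.719 in the knockouts and 0.5 to 0.6 in the reference. A parent strain common to the knockouts could be another, and these arrays separate neither from the loss of a factor.

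For the tfbG strain 17.5% of the 1264 features above the median intensity passed, 34 higher and 187 lower. That share does not decide on the shift of dim features. On the tfbG array with the strain in Alexa 532, only 603 features stood out in that dye. In the dimmest 25% the shift may account for the higher features, since the unfilled positions moved by a median of 0.57 and those features by 0.27. Growth phase cannot be told apart from the tagged factor, as 0 knockout or reference cultures were in late stationary phase.

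The count of features between tbp and tfb knockouts did not exclude chance. At an unadjusted p under 0.05 the real split gave 185 features, and 9 of the 35 splits of the 7 strains gave as many, the highest of the others 397. That split set tbpA, tbpC and tfbD against the rest, and their arrays with the strain in Alexa 647 also had the fewest features above the unfilled positions in Alexa 532 among the knockouts in that orientation, 452, 541 and 443 against 781 to 1472, so that array quality stays open as its cause.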

How the results depend on the processing

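The 18 features followed in the shared and 25 in the tfbG comparison kept their direction under the alternatives run, with 2 exceptions in the shared change: hisF stood at -0.0460 with Alexa 532 arrays alone and truA at 0.66 with Alexa 647 arrays alone. Beside them, 64 of 370 values of the shared change lost the threshold with their direction kept, and 78 of 519 of the tfbG comparison. The causes of the differences were not tested. Part of the 370 and 519 values could not have turned, and how many was not counted. Most of these features were picked for the same sign in every knockout or for lying outside the knockouts' range. For those, leaving out knockouts cannot turn the direction. Changing the eBayes prior or leaving out the dimmest 25% does not alter a fitted value. In such runs a kept direction is no evidence of stability. The shared count, 297, was 686 without background correction, 155 with the deposited values, 949 and 1094 with Alexa 532 or Alexa 647 arrays alone, 458 in the low scanner setting, 161 without tfbB and tfbD, and 139 to 298 with 1 knockout left out. The tfbG count, 330, became 704, 205, 657, 53 and 530 under the first 5 of these. The share of higher calls moved from 60.3% to 70.3% for the deposited values and 43.6% once these were centred, to 37.1% with Alexa 532 arrays and to 71.8% with only features above the unfilled positions. For tfbG it moved from 30.6% to 50.6% without background correction, 17.6% with the deposited values, 43.1% and 15.1% with Alexa 532 and Alexa 647 arrays, 43.5% with loess per block and 18.5% above the unfilled positions. Between tbp and tfb knockouts 1 feature passed under median centring. The single knockouts, with 1 feature in all, had 10 without background correction, 0 under median centring, 70 with the deposited values (tfbA), 73 without the dimmest 25%, 554 and 0 with Alexa 532 and Alexa 647 arrays, 15 with the median of spots, 3 with arrays as units, 14 in the low setting, 0 with the deposited values centred, 2 with loess per block, 87 with only features above the unfilled positions and 0 to 1 with 1 knockout left out. The 2-fold total over the 8 strains, 153, became 48 with 2-fold on both arrays, 15 without background correction, 25 and, centred, 27 with the deposited values, 1935 and 2242 with Alexa 532 and Alexa 647 arrays, 59 in the low setting, 86 with loess per block and 74 with only features above the unfilled positions. The highest similarity was 0.129 without tbpA and 0.162 without tbpC, each of which removes the most similar pair itself. With any other knockout left out it ranged from 0.243 to 0.287. The density relation fell to -0.00436 without 2 strains. Features that did not pass turned sign: 1921 to 0.17 and, centred, 0.10 and 3261 to -0.0307 and -0.0184 with the deposited values, 4733 to -0.0153 with Alexa 647 arrays, and 4233 to 0.15 with loess per block, the last 3 not well above the unfilled positions on any knockout array. With named genes as the background, camera's direction for DNA replication in the tfbG strain turned (adjusted p = 0.976) and chemotaxis passed (adjusted p = 0.00499), as did purine and pyrimidine synthesis in the tfbB knockout (adjusted p = 0.0250). The citric acid cycle in the tfbG strain lost its call with an estimated correlation (adjusted p = 0.0722). Leaving out plasmid genes, matching lists on product text and all alternatives for the targeted genes were not run, for want of names. The low scanner setting, the centred values, loess per block, the filter on unfilled positions, leaving out tfbB and tfbD and the named background were chosen after seeing the data.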

Other observations

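Lists with fewer than 5 measured genes add some detail on the tfbG strain. Of the arginine fermentation genes, arcC rose by 1.30 against the knockouts while arcA, arginine deiminase, stood at 0.30 (SE 0.18, adjusted p = 0.29), with some of its spots saturated. Of 4 cobalamin synthesis genes cbiG fell by 0.66 (adjusted p = 0.028), and cbiT, cbiQ and cobN stood at -0.50, -0.21 and -0.11. None of 4 genes in the list of rhodopsins and their regulators passed: hop stood at -0.54, bat at -0.16, sop1 at -0.15 and sop2 at -0.05. The oxidative stress genes msrA and dpsA stood at 0.51 and 0.02, with 12.5% of the dpsA spots saturated, infB, a translation initiation factor, at -0.01, nuoL of the respiratory chain at 0.09 and phoU at -0.73 (adjusted p = 0.28).

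Feature 4433, without a symbol here, had a log2 ratio of -1.91 in tbpA, -1.90 in tbpC, -2.04 in tbpD, -1.62 in tfbA, -2.02 in tfbB, -2.28 in tfbC and -2.13 in tfbD, but -0.40 in the tfbG strain, and the next lowest shared change was -1.03. A hypothesis formed after seeing it is that a gene lost or weakened in a common parent of the knockouts could give this. Its strain channel was well above the unfilled positions on 6 of 14 knockout arrays and its reference channel on 13 of 14, which neither excludes the hypothesis nor bears it out, since a full loss would leave 0 of 14 and the feature has no name. Feature 5161 lay at -1.03 in the knockouts and 0.89 in the tfbG strain.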
